A study of Mus musculus with 4 samples.

How the data were processed

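Total RNA from embryonic day 16.5 cortex of C57BL/6 mice was sequenced in 4 libraries. Of these, 2 carry the wild-type label (replicates 1 and 4) and 2 carry the label of a conditional knockout of the histone variant H2A.Z.2 (replicates 1 and 2, called cKO here). H2A.Z.2 is encoded by H2afv. The labels do not say whether libraries came from separate embryos or litters, so p-values measure the spread between these libraries, part of which can be technical.

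The submitters' processing notes name Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.0 and the mouse build mm9. The authors deposited 2 tables, each comparing 1 cKO library with 1 wild-type library: cKO replicate 1 with wild type replicate 4, and cKO replicate 2 with wild type replicate 1. Columns were matched to samples by their headers, which hold the sample titles. The description labels differ from these headers: that of wild type replicate 4 names the table of cKO replicate 2 and wild type replicate 1, and that of cKO replicate 2 names a comparison with wild type replicate 4. Per the file headers, each table holds raw read counts per gene, normalised values, a fold change, its log2, a p-value and an adjusted p-value. The deposited normalised values equalled the count scaled to the library total (CPM) for all genes above 0 (tolerance 1e-06), and 0.5 reads stood for a count of 0. The authors' deposited fold change (a ratio), log2 fold change and p-value are each for 1 library against 1 library. The deposited column that marks significant genes followed an adjusted p below 0.05 with an absolute log2 fold change above 1, for all genes listed, whereas the design text names a p below 0.05. Whether counting used strand is not given in the sources used here, so a gene and an antisense partner cannot be told apart. Gene positions in the deposited tables matched GRCm38: of 22574 genes found in GENCODE release M21, 92.2% had the same start and end. Coordinates printed here are those of the tables, on GRCm38.

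Each table listed a gene when both of its libraries held at least 1 read, or when either held at least 5, a rule read from the values. A gene left off a table can therefore have up to 4 reads in either of its libraries. The 2 tables held 22619 genes together, and 19844 were in both. The 2775 genes in 1 table only were not used in the main test. They were added with unlisted values as 0 in an alternative chosen after seeing the data. A line of each table had been emptied beforehand, and that item and some others are not reported here. Library totals were 17288472 reads for wild type replicate 1, 16625181 for wild type replicate 4, 17940659 for cKO replicate 1 and 17512103 for cKO replicate 2.

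Counts as deposited were joined by gene identifier in Python 3.11.15 and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM normalisation, filterByExpr with a minimum count of 10, two-sided, Benjamini-Hochberg adjustment at 5% FDR). This left 16269 genes, a biological coefficient of variation of 0.194 and 2 residual degrees of freedom. CPM values in the text are TMM-normalised. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 3, preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over 28 lists of at least 5 measured members. The lists covered cortical progenitors, neurons, glia, blood and vessel cells, neighbouring tissues, the cell cycle and stress responses. The same lists were tested with an estimated correlation and with fry. The camera p given with an estimated correlation is unadjusted. Its adjusted value was 0.883 for each of the 8 lists called with the preset correlation.

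The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named H2afv, H2afz and Cxcl14, genes past 5% FDR, up to 4 members per list with the smallest unadjusted p, sex-linked genes, and the 5 genes each way with the largest mean log2 fold change among those past the authors' thresholds in both tables. Genes outside the rule are said to have been chosen after their values were seen. Alternatives were DESeq2 1.42.0, other size factors, no filter or a mean CPM of at least 1, the deposited table as a block, each library left out in turn, the X and Y chromosomes left out, and the p and log2 thresholds of the series.

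The pipeline was tested on simulated data at the libraries' own means and depths. At the observed coefficient of variation of 0.194, edgeR found 29.7% of 300 genes changed 2-fold and 95.7% of 300 genes changed 4-fold. There were 14 false calls over 3 draws. Every simulated gene had this same variation, and no simulated library stood apart. These shares therefore do not hold for genes that vary more between libraries of a group. In the data Hbb-y, at a log2 fold change of -6.16, was not called (edgeR adjusted p = 0.956). For lists of 20 genes raised 1.5-fold, camera found 10 of 10 with the preset correlation, calling 1 of 300 unchanged lists. Simulated genes varied independently. In the data the estimated correlation ran from 0.148 (radial glia) to 0.985 (G2 and M phase) in the 8 lists called. The false-call count does not hold for such lists, and their camera p-values with the preset correlation can be too small. With an estimated correlation camera found 0 of 10 simulated lists. A list lost under that setting in a comparison of 2 against 2 is therefore not shown to be unchanged. The smallest p that an exact permutation test allows for 2 libraries against 2 is 0.333. Figures were drawn with matplotlib 3.10.9.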

Results

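The series asks how neural progenitor cells, through the histone variant H2A.Z.2, act on microglia in the embryonic brain. Its RNA-seq compares cortex of H2A.Z.2 conditional knockout and wild-type mice at E16.5, with 2 libraries in each group. The 4 libraries held 16625181 to 17940659 reads assigned to genes, with 21027 to 21219 genes detected in each. Mitochondrially encoded genes took 2.08% to 2.54% of the reads. The 4 libraries were distinct: the chi-square per gene between pairs ran from 6.53 to 42.6.

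H2afv, the targeted gene (ENSMUSG00000041126, chromosome 11, 6427229 to 6444443, minus strand), was at 136 CPM in wild type replicate 1, 222 CPM in wild type replicate 4, 128 CPM in cKO replicate 1 and 127 CPM in cKO replicate 2. The wild-type mean was 179 ± 60.6 CPM (SD, n = 2) against 127 ± 0.528 CPM (SD, n = 2), a log2 fold change of -0.49 (SE 0.23, 95% confidence interval -1.05 to 0.06, edgeR adjusted p = 0.956). Against wild type replicate 1 alone the cKO libraries differed by -0.09 and -0.10. Without wild type replicate 4 the log2 fold change was -0.09, and without wild type replicate 1 it was -0.80. Each of these fits held a lone wild-type library, which has no spread of its own. Both libraries labelled cKO lay below both wild-type libraries, and the 2 groups failed to overlap in 31.6% of all genes tested. The authors' deposited log2 fold changes of H2afv were -0.83 against wild type replicate 4 and -0.14 against wild type replicate 1. The gene's count hardly separated the cKO label from wild type replicate 1, so these are called the libraries labelled cKO. The counts cover the whole gene, the labels do not say which exons are deleted, and reads from exons outside a deletion would not show it. H2afz, which encodes the paralog H2A.Z.1, had 283 and 524 CPM in wild type and 316 and 279 CPM in the libraries labelled cKO (log2 fold change -0.44, SE 0.28), and its log2 fold change was 0.075 without wild type replicate 4.

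No single gene passed 5% FDR between the libraries labelled cKO and wild type. Of 16269 genes tested with edgeR, 0 were called, the smallest adjusted p was 0.956, and 272 had an unadjusted p below 0.05, with 110 higher and 162 lower. These 272 were 1.67% of the genes tested, where about 5% would be reached with no change at all. DESeq2 also called 0, with 401 at an unadjusted p below 0.05. The 2 groups did not overlap in 5146 genes, or 31.6%, where chance gives 33.3%. At the series' own thresholds of an unadjusted p below 0.05 and an absolute log2 fold change above 1, 39 genes were higher and 49 lower. Without wild type replicate 1 the call count was 1849 (903 higher, 946 lower). Without cKO replicate 1 it was 1, which was Tagln2, a gene outside the naming rule that was picked out after its values were seen.

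Wild type replicate 4 stood apart from the other 3 libraries. The first principal component, with 63.6% of the variance, placed it at 53.7 and the others between -25.9 and -10.0. It differed by more than 2-fold in 1388 genes from wild type replicate 1, whereas replicate 1 differed in 369 and 373 genes from the libraries labelled cKO. Its share of reads on Gm23935, CT010467.1 and Lars2, a sign of ribosomal RNA in a library and chosen after their values were seen, was 0.383% against 0.0346% to 0.0480% elsewhere.

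The medians of lists of dividing progenitors were highest in wild type replicate 4, and these lists were lower in the libraries labelled cKO than in the wild-type mean. Not every member was highest there. The radial glia genes Tnc, Hopx, Fabp7 and Slc1a3, chosen after their values were seen, were higher in cKO replicate 1 than in wild type replicate 4. Against wild type replicate 1 alone, cKO replicate 1 had a median difference of 0.029 for G2 and M phase, 0.039 for S phase, -0.0031 for intermediate progenitors and -0.18 for radial glia genes. The differences of cKO replicate 2 were -0.25, -0.17, -0.16 and -0.27 in the same order. Of the 21 measured G2 and M phase genes all 21 were lower, with a median log2 fold change of -0.72. The list fell (camera adjusted p = 5.34e-12, unadjusted p = 0.218 with an estimated correlation). Ccnb1, a mitotic cyclin, was at 47.0 and 100 CPM in wild type replicates 1 and 4 and at 40.9 and 38.0 CPM in the libraries labelled cKO (log2 fold change -0.90, SE 0.34). All 20 S phase genes were lower, among them the replicative helicase gene Mcm3 at -0.72 (SE 0.29). That list fell with a median of -0.59 (camera adjusted p = 3.05e-09, unadjusted p = 0.257 with an estimated correlation). Radial glia genes fell with a median of -0.44, 18 of 20 being lower (camera adjusted p = 2.77e-07, unadjusted p = 0.0902 with an estimated correlation). Pax6, a radial glia transcription factor, was at 61.3 and 82.4 CPM in wild type and 51.2 and 53.6 CPM in the libraries labelled cKO, and Gli3 and Sox2 had log2 fold changes of -0.90 and -0.62. All 12 intermediate progenitor genes were lower, with a median of -0.55 (camera adjusted p = 2.07e-06, unadjusted p = 0.251 with an estimated correlation). They included Eomes at -0.60 (SE 0.19) and Neurog2 at -0.78 (SE 0.28). In these 4 lists, 0 genes passed 5% FDR, whether adjusted over all genes tested or adjusted over the list alone. The list medians relative to the gene mean were 0.82 for G2 and M phase and 0.74 for S phase in wild type replicate 4, and between -0.45 and -0.15 in the other 3 libraries. Without wild type replicate 4, the S phase and intermediate progenitor lists were no longer called (camera adjusted p = 0.0872 and 0.0508), and the G2 and M phase and radial glia lists stayed called as lower (0.000813 and 6.34e-09), the former with cKO replicate 2 below and cKO replicate 1 not below wild type replicate 1.

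**Figure D1:**
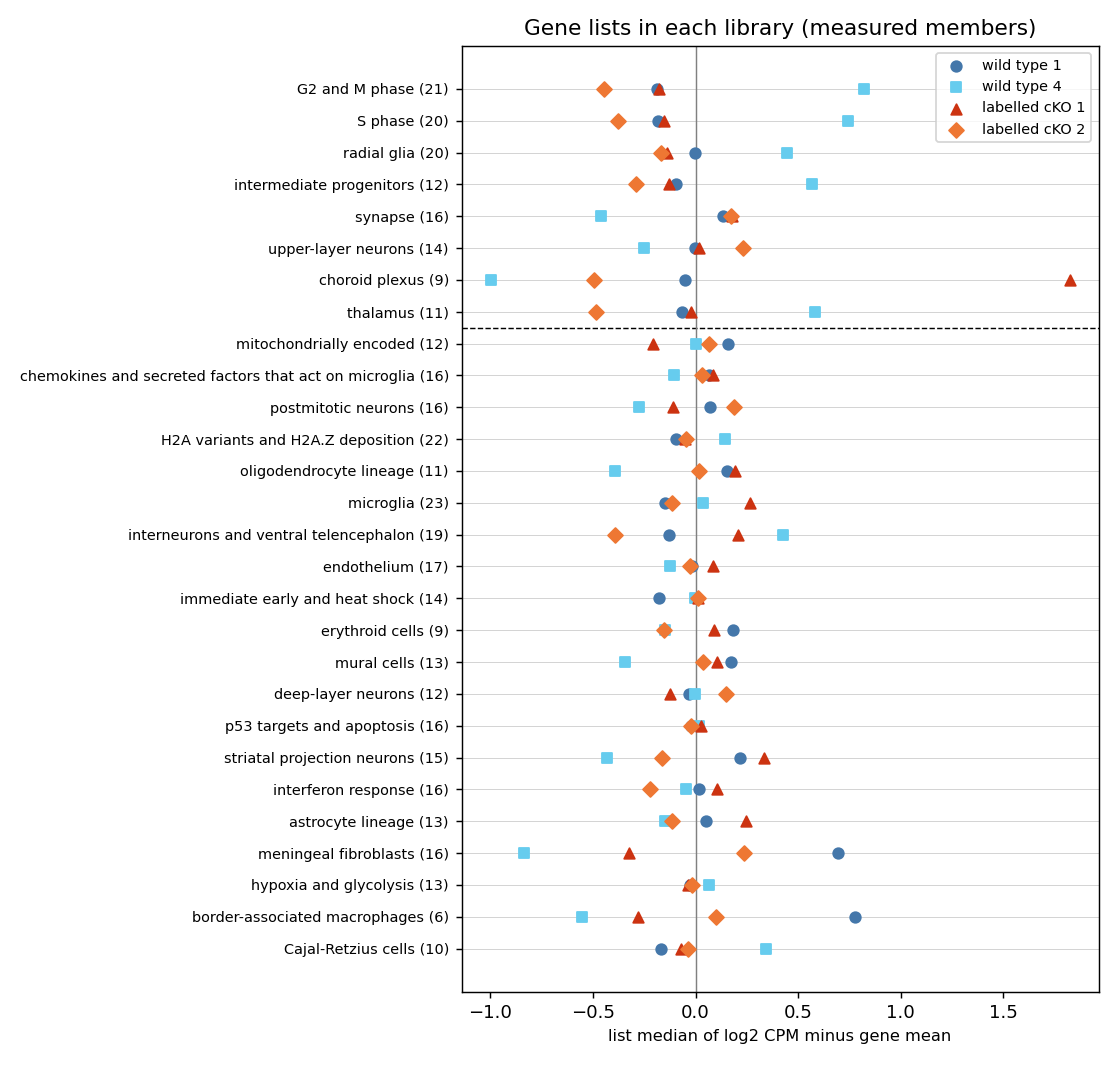
For each of 28 gene lists (rows, measured members in brackets) the horizontal axis gives the median over members of log2 CPM minus the gene's mean over the 4 libraries, with 1 point per library. Lists above the dashed line passed 5% FDR in camera with the preset correlation, and wild type replicate 4 lies apart in the cell-cycle lists (0.82 and 0.74).

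The synapse and upper-layer neuron lists moved the other way. The synapse list rose with a median of 0.28, 15 of 16 genes being higher (camera adjusted p = 1.76e-05, unadjusted p = 0.270 with an estimated correlation). Upper-layer neuron genes rose with a median of 0.26, 12 of 14 being higher (camera adjusted p = 0.000204, unadjusted p = 0.216 with an estimated correlation). Cux2, a transcription factor of upper-layer neurons, was at 196 and 135 CPM in wild type and 207 and 241 CPM in the libraries labelled cKO (log2 fold change 0.44, SE 0.20). No member of either list passed 5% FDR, over all genes or adjusted over the list alone. Against wild type replicate 1 alone, the median difference of the synapse list was 0.044 in cKO replicate 1 and 0.076 in cKO replicate 2, and that of upper-layer neurons was -0.020 and 0.27. Without wild type replicate 4 the synapse list was no longer called (camera adjusted p = 0.434), and upper-layer neurons stayed called (0.00306), with cKO replicate 2 above and cKO replicate 1 not above wild type replicate 1. Without cKO replicate 2 upper-layer neurons were no longer called (camera adjusted p = 0.0721).

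Markers of the thalamus were lower and those of the choroid plexus higher. Of 11 thalamus genes 9 were lower, with a median of -0.36 (camera adjusted p = 0.0148, unadjusted p = 0.259 with an estimated correlation). Lhx9, a transcription factor of the diencephalon, was at 16.1 and 24.4 CPM in wild type and 10.7 and 4.32 CPM in the libraries labelled cKO. Of 9 choroid plexus genes 7 were higher, with a median of 1.67 (camera adjusted p = 0.0144, unadjusted p = 0.381 with an estimated correlation). Ttr, which encodes the secreted thyroxine carrier transthyretin, was at 466 CPM in cKO replicate 1 and 48.3 CPM in cKO replicate 2, against 26.7 and 0.473 CPM in wild type. In these 2 lists 0 genes passed 5% FDR, over all genes or adjusted over the list alone. Without cKO replicate 1 the choroid plexus list was not called and turned lower (camera adjusted p = 0.816), and the thalamus list was not called without wild type replicate 4 (0.685) or without cKO replicate 2 (0.188).

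Markers of microglia, the cell type the series addresses, did not pass the test in either direction. Of 23 measured microglia genes 14 were higher and 9 lower, with a median of 0.14 (camera adjusted p = 0.230). Of members chosen after their values were seen, Csf1r, the receptor for colony-stimulating factor 1, was at 10.5 and 10.5 CPM in wild type and 12.8 and 7.82 CPM in the libraries labelled cKO. Cx3cr1, the fractalkine receptor, was at 3.63 and 5.32 CPM against 5.98 and 4.55 CPM. Tyrobp, a signalling adaptor, had a log2 fold change of 0.65 (SE 0.44), with its highest level, 3.08 CPM, in cKO replicate 1 and 1.69 CPM in cKO replicate 2. The microglia list was called higher without wild type replicate 4 (camera adjusted p = 0.0453) and without cKO replicate 2 (0.00355), and turned lower, uncalled, without cKO replicate 1 (0.745). Its median was highest in cKO replicate 1 (0.26), the library in which the choroid plexus median was also highest (1.82). Among 16 measured chemokines and secreted factors that act on microglia, 11 were higher (camera adjusted p = 0.0803). Cxcl14, a chemokine, was at 14.4 and 17.4 CPM in wild type and 20.6 and 23.7 CPM in the libraries labelled cKO, a log2 fold change of 0.48 (SE 0.20, 95% confidence interval -0.01 to 0.96, edgeR adjusted p = 0.956). Mif was at 310 and 289 CPM against 367 and 355 CPM (log2 fold change 0.27, SE 0.12). In these 2 lists 0 genes passed 5% FDR, over all genes or adjusted over the list alone.

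**Figure D2:**
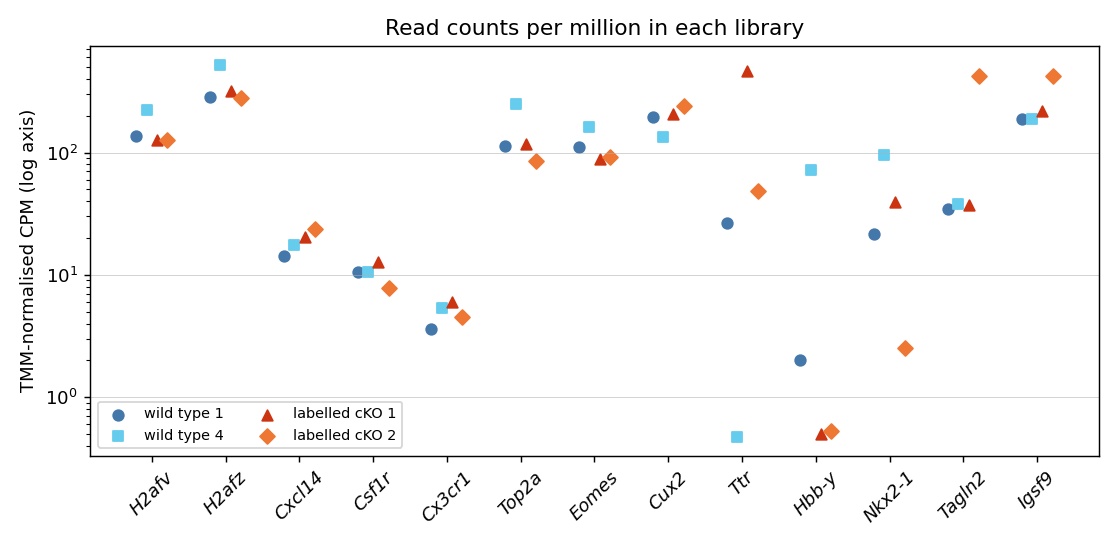
TMM-normalised CPM (vertical axis, log scale) of 13 genes, with 1 point per library. H2afv is at 136 CPM in wild type replicate 1 and at 127 and 128 CPM in the libraries labelled cKO, Ttr is highest in cKO replicate 1 at 466 CPM, and Csf1r lies between 7.82 and 12.8 CPM. Csf1r, Cx3cr1, Top2a, Nkx2-1, Tagln2 and Igsf9 were chosen after their values were seen.

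None of the other 18 lists passed 5% FDR in the main test. With the deposited table as a block, camera called interneuron genes (adjusted p = 0.00725) and mitochondrial genes (0.0422) lower and postmitotic neuron genes higher (0.0207). Mitochondrially encoded genes were lower in 11 of 12 members (camera adjusted p = 0.0612). Postmitotic neuron genes were higher in 12 of 16 (0.103), deep-layer neurons in 6 of 12 (0.703) and Cajal-Retzius cells in 5 of 10 (0.946). Interneuron and ventral telencephalon genes were lower in 14 of 19 (camera adjusted p = 0.276), and striatal projection neuron genes in 8 of 15 (0.787). H2A variants and H2A.Z deposition factors were lower in 16 of 22 (0.137), with Anp32e, an H2A.Z chaperone, at a log2 fold change of -0.41 (SE 0.21). Anp32e was at 157 and 243 CPM in wild type replicates 1 and 4 and 153 and 148 CPM in the libraries labelled cKO. The list median relative to the gene mean was 0.14 in wild type replicate 4 and -0.096 in wild type replicate 1. In the libraries labelled cKO it was -0.049 and -0.046, above wild type replicate 1. Oligodendrocyte lineage genes were higher in 8 of 11 (0.205) and astrocyte lineage genes in 8 of 13 (0.913), with Gja1, a gap junction gene of astrocytes, at 25.6 and 24.3 CPM in wild type and 15.1 and 14.6 CPM in the libraries labelled cKO. Endothelium genes were higher in 10 of 17 (0.285), mural cell genes in 10 of 13 (0.577) and erythroid genes in 4 of 9 (0.498). Hbb-y, an embryonic globin gene, was at 72.4 CPM in wild type replicate 4 and at 0.503 to 2.02 CPM in the other 3 libraries. Meningeal fibroblast genes were lower in 11 of 16 (0.946) and border-associated macrophage genes in 4 of 6 (0.946), both with a median and mean below 0 and an upward camera direction. Striatal genes had a median of -0.01 with a mean of 0.02 and an upward direction. Immediate early and heat shock genes were higher in 8 of 14 (0.440), p53 targets in 8 of 16 (0.784), interferon response genes in 7 of 16 (0.913) and hypoxia and glycolysis genes in 7 of 13 (0.946). In these lists 0 genes passed 5% FDR over all genes or adjusted over the list alone. Without wild type replicate 4, camera called the mitochondrial (adjusted p = 5.59e-07), meningeal (1.86e-09), border macrophage (0.000200) and erythroid (0.000813) lists lower and Cajal-Retzius cells higher (0.0397). Without wild type replicate 1 it called meningeal (adjusted p = 0.00660) and postmitotic neuron genes (0.00660) higher, and H2A variant (0.00423) and interneuron genes (0.0134) lower. Without cKO replicate 1 it called postmitotic (adjusted p = 6.80e-05) and deep-layer neurons (0.0177) higher, and interneuron (4.98e-07) and erythroid genes (0.0177) lower. Without cKO replicate 2 it called oligodendrocyte (adjusted p = 0.0290), astrocyte (0.0461), endothelium (0.0425) and striatal genes (0.0105) higher and mitochondrial genes lower (0.000102). Xist was at 561 to 669 CPM in all 4 libraries (log2 fold change -0.09, SE 0.13), and Tsix, Ddx3y, Eif2s3y, Kdm5d and Uty were listed in neither table.

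In the authors' deposited tables, each of 1 library against 1, many genes passed the series' thresholds and few were shared. The authors' deposited table of cKO replicate 1 against wild type replicate 4 held 1059 genes higher and 990 lower, and that of cKO replicate 2 against wild type replicate 1 held 304 higher and 636 lower. By the authors' adjusted p, which the deposited significance column follows, the authors' deposited tables held 961 higher and 898 lower in the first and 98 higher and 245 lower in the second. Of 19844 genes in both, 29 were higher in both tables and 55 lower in both, where independent lists would share 14.1 and 26.0. A further 88 genes went in opposite directions, where independent lists would give 42.0. Otp, a transcription factor of the hypothalamus, was lower in both of the authors' deposited tables, with 69 and 352 reads in wild type replicates 1 and 4 and 73 and 0 reads in the libraries labelled cKO. The vasopressin gene Avp had 21 and 27 reads in wild type and 5 and 0 in the libraries labelled cKO. Hbb-y had log2 fold changes of -7.20 and -1.98 in the authors' deposited tables. Those of Rgs13, -3.57 and -3.83, rest on 1 read in each library labelled cKO, against 14 and 11 reads in wild type. Actc1 had 8 reads in each wild-type library and 0 in those labelled cKO. Among genes higher in both, Slc4a5, a bicarbonate transporter gene of the choroid plexus list, had 1 and 0 reads in wild type and 50 and 10 in the libraries labelled cKO, and Xlr4b had 0 and 3 against 27 and 10. Gm26519, Gm14756 and Gm7467 had at most 1 read in wild type and 5 to 9 in the libraries labelled cKO. Where a library had 0 reads, the authors' fold change rests on the 0.5 reads put in its place, so none is given here. With the authors' adjusted p the shared count was 47.

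Fold changes in the 2 pairs hardly tracked each other across genes. Over 16269 genes, which are not independent replicates, the log2 fold change of cKO replicate 1 over wild type replicate 4 correlated with that of cKO replicate 2 over wild type replicate 1 at Pearson r = 0.026 and Spearman rho = 0.043. The same sign was seen in 52.6% of genes.

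**Figure D3:**
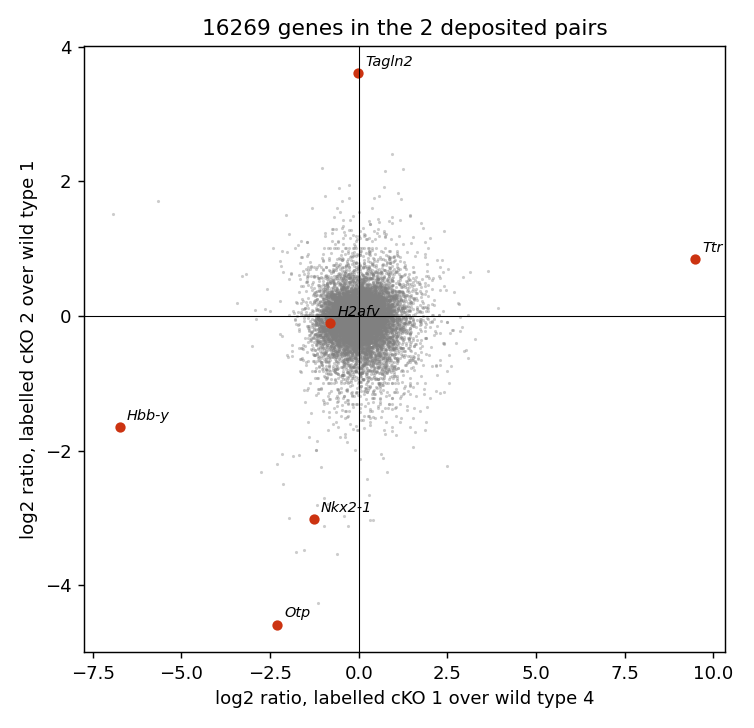
Each of 16269 genes is a point, with the log2 ratio of cKO replicate 1 over wild type replicate 4 on the horizontal axis and of cKO replicate 2 over wild type replicate 1 on the vertical axis. Across genes Pearson r is 0.026, and H2afv lies at -0.80 and -0.10, within the bulk of the points. Tagln2 and Nkx2-1 were chosen after their values were seen.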

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

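The test that added genes in 1 table only was chosen after seeing the data. The count of genes past 5% FDR was 0 there, under DESeq2, other size factors, no filter, a mean CPM of at least 1, the deposited table as a block, and without the X and Y chromosomes. At an unadjusted p below 0.05 with an absolute log2 fold change above 1 it was 88. Leaving out each library gave 0 to 1849 genes: 1849 without wild type replicate 1, 1 without cKO replicate 1, and 0 without either other library; a lone library was then assumed to vary like the other group. H2afv ranged from -0.80 to -0.092 over the left-out libraries. Gene lists past 5% FDR numbered 8, and 0 with an estimated correlation, 0 with fry and 0 with fry in either direction. Of the 8, the count kept was 4 without wild type replicate 4, 7 without cKO replicate 1, 6 without cKO replicate 2 and 8 without wild type replicate 1. Genes past the authors' thresholds in both tables numbered 47 with the adjusted p and 228 with the fold threshold lowered to 1.5. The correlation between pairs was -0.1725 with crossed pairing, -0.0021 with no filter and 0.0459 at a mean CPM of at least 1. With the deposited table as a block, edgeR gave 920 genes at an unadjusted p below 0.05 against 272 without it, and camera called 11 lists, the 8 and 3 more. No paired analysis was possible because the groups share only replicate number 1: the block follows the authors' choice of libraries, which no label ties to a litter or day. The cause was not tested for any of these.

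Single genes, none called in the main test, changed sign as libraries were left out, with log2 ranges of -0.81 to 0.075 (H2afz), -3.59 to 0.76 (Lyve1), -1.55 to 1.45 (F13a1), -0.026 to 0.82 (Fcgr3), -0.00069 to 0.37 (Tle4), -0.72 to 0.42 (Nxph4), -0.23 to 1.34 (Crym), -0.024 to 0.64 (Ramp2), -3.84 to 0.57 (Hba-x), -0.00036 to 0.68 (Alas2), -1.05 to 0.17 (Actl6a), -0.62 to 0.012 (Pwwp2a), -0.76 to 0.14 (Gapdh), -0.60 to 0.032 (Foxc1), -0.38 to 0.020 (mt-Nd2), -0.061 to 1.55 (Higd1b), -0.21 to 1.33 (Gpr17) and -0.19 to 0.033 (Xist). Of 1244 values of 114 named genes under the alternatives, 1164 kept direction and side of the threshold, 19 reversed and 61 passed the threshold only there.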

Other observations

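These tests were chosen after the result was seen: both of tissue outside the dorsal pallium, both genotype tests, cells of the listed non-neural types, and the change at the locus. The genotype test of the locus was widened to both genes after Tagln2 alone had been tested, and tests of stage, length and GC content, and the second choroid plexus list were set before their results. Some genes of the hypothalamus and ventral forebrain, singled out after their values were seen, differed widely within each label. Nkx2-1, a transcription factor of the ventral forebrain, was at 21.5 and 95.5 CPM in wild type replicates 1 and 4, at 39.7 CPM in cKO replicate 1 and at 2.51 CPM in cKO replicate 2. Fezf1 had 132, 271, 127 and 4 reads in the same order, and Lhx8 was at 8.71, 31.3, 17.2 and 1.11 CPM. Nkx2-1, Fezf1, Otp and Sim1 were among the 55 genes lower in both of the authors' deposited tables, whereas Pomc, another gene of the hypothalamus, had 30 and 32 reads in wild type and 47 and 27 in the libraries labelled cKO. Fezf1, Sim1 (14 and 43 reads in wild type, 8 and 0 in the libraries labelled cKO) and Avp were lower in both libraries labelled cKO than in both wild-type libraries, each with an edgeR adjusted p of 0.956, and Nkx2-1, Lhx8 and Otp were not.

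The labels did not overlap in 31.6% of genes, where chance gives 33.3%, and the examples that follow were picked out afterwards, each with an edgeR adjusted p of 0.956 in a 2 against 2 comparison. Malat1, a nuclear long noncoding RNA, was at 238 and 242 CPM in wild type and 164 and 152 CPM in the libraries labelled cKO (log2 fold change -0.60, SE 0.12). Eps8l1 was at 8.25 and 6.44 CPM against 14.5 and 19.0 CPM (1.19, SE 0.26). Xlr3b had 52 and 77 reads against 293 and 132, and its reads are uncertain because near-identical copies lie beside it on the X chromosome. At an unadjusted p below 0.05 the labels gave 272 of 16269 genes with edgeR, or 1.67%, where about 5% would be reached with no change at all. Grouping wild type replicate 1 with cKO replicate 1 against the other 2 libraries gave 394. The most, 922, came from wild type replicate 1 with cKO replicate 2 against wild type replicate 4 with cKO replicate 1. That grouping follows the 2 deposited tables. Each grouping had 0 genes past 5% FDR, and 3 groupings are too few for a share under 0.05.

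In wild type replicate 4, the medians of the proliferation and progenitor lists and the embryonic globins were higher than in the other 3 libraries. Not every member was: Tnc, Hopx, Fabp7 and Slc1a3 of the radial glia list were higher in cKO replicate 1. A bias by transcript length and GC content is argued against by its trend over all genes: 94.8% of the median excess of the 73 cell-cycle and progenitor genes was left after its removal (0.96 before, SD 0.51, and 0.91 after, SD 0.51). More tissue from outside the dorsal pallium is argued against only as the source of the dorsal progenitor genes. Their median was 0.93 above the highest other library (1.00 for the 4 of 8 outside the progenitor lists). These genes mark the dorsal pallium, so their rise does not tell whether other tissue was also present. Such tissue as a source of the cell-cycle genes stays open. The hypothalamus list was highest in wild type replicate 4, by 1.38 where the other 3 libraries spanned 3.05. The thalamus (0.58) and interneuron (0.42) medians were highest there too, while the striatal (-0.43), choroid plexus (-0.999) and meningeal (-0.84) medians were lowest there. An earlier developmental stage is a candidate explanation: the median of 10 early-stage genes minus that of 14 late-stage genes, 0 of them in the other lists, was 0.51 above the highest other library, where the other 3 spanned 0.091. However, the label gives the same embryonic day to all 4, and Ccnd1 of the early list is also a cell-cycle gene. Hbb-y made up 17.5% of beta-globin reads against 0.0941% to 0.405%. That share belongs to the pattern to be explained and is not separate support for an earlier stage.

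The choroid plexus list median was highest in cKO replicate 1. Its member Otx2, chosen after its values were seen, was lower there than in wild type replicate 4. The genotype as the whole cause is argued against by cKO replicate 2, where the list's median was -0.34 relative to wild type replicate 1, against 1.92 in cKO replicate 1 (SD of the difference between members 0.67). This holds only if both libraries labelled cKO carry the deletion, which the H2afv counts did not show. A smaller part from the genotype stays open: relative to wild type replicate 4 the median of cKO replicate 2 was 0.55, and 3 of the 9 members (Ttr, Folr1 and Clic6) were higher in both libraries labelled cKO than in both wild-type libraries, as were Slc4a5 and Kcne2, the latter chosen after its values were seen (16 and 6 reads in wild type, 116 and 27 in the libraries labelled cKO). Carry-over of choroid plexus tissue into cKO replicate 1 may explain the pattern: a second list, of which 8 genes were measured, had a median 0.66 above the highest other library. That median was 0.67 in cKO replicate 1, -0.13 in cKO replicate 2, and 0.0056 and -0.46 in wild type replicates 1 and 4. Any cause that raised choroid plexus genes in cKO replicate 1 would raise this list too, so the list does not single out carry-over. Ttr, the most abundant of these transcripts, was at 466 CPM there, and Foxj1, in the second list, is also expressed by ciliated cells outside the choroid plexus.

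Tagln2 and its neighbour Igsf9 were raised in cKO replicate 2, at 424 CPM against 34.8 to 37.9 CPM and at 420 CPM against 189 to 217 CPM. Cells of the 7 non-neural types with a list are argued against, since no list had a median in that library above the highest of the others (at most -0.11). Types without a list were not tested. In cKO replicate 1 neither gene was more than 0.19 above the higher wild-type library. This does not decide on the genotype. Both genes were picked for their rise in cKO replicate 2, and H2afv hardly separated the cKO label from wild type replicate 1. A change limited to the locus is a candidate explanation: both genes lie on the plus strand of chromosome 1 (172481788 to 172498878 and 172500047 to 172507380), 1168 bp apart. Of 22 other tested genes within 1 Mb, 0 left the 1.5-fold range of the other libraries. Only 76 of 16269 genes tested rose over 1.5-fold in cKO replicate 2, so few or none of any 22 genes would rise. The count of 0 therefore does not show that the change is limited to the locus. Tagln2 and Igsf9 were the only adjacent pair of 16247 with both members over 1.5-fold in cKO replicate 2. There 76 genes were over 1.5-fold, and the number of such pairs that chance would give was not computed. Read-through, a structural variant and a mapping effect could each give a change limited to the locus, and no value here separates them.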
